A study of Mus musculus with 15 samples.

How the data were processed

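Total RNA was isolated with a lipid tissue kit from mixed corpus callosum and neocortex of 15 mice, and libraries were made from 1 µg of RNA with a stranded total RNA kit after ribosomal RNA depletion, per the labels' protocols. The first line of each file names a 3 prime mRNA analysis instead. Which of these was used could not be settled. Reads were handled with bcl2fastq, Trim Galore 0.6.6, STAR 2.6.1d and Salmon 1.4.0 against mm10, per the submitters' processing notes. Their order, the annotation and whether quantification used strand are not given in the sources used here, so genes that overlap on opposite strands are not told apart.

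The authors deposited 3 tables, 1 for each pair of groups. Each holds TPM per mouse (transcript abundance scaled to a fixed total per library, per the file headers), and a mouse's TPM were identical in the tables that hold it (largest difference 0). The tables also hold a log2 fold change with its standard error on the log2 scale, a statistic (a score, the fold change over its standard error), and a p-value and adjusted p-value of the authors' own comparison, per the file headers. A mean level over libraries was deposited as well and served to rank genes. The test and the adjustment behind the deposited p-values are not given in the sources used here. The deposited log2 fold changes were set against fold changes of mean TPM with up to 3 mice left out (176 choices per comparison, genes with a deposited mean level of at least 200). The closest match left out vehicle mouse 1, siponimod mouse 1, or both, in the comparisons that hold them, with a median difference of 0.0151, 0.0152 and 0.0162 log2. The next best choices gave 0.0246, 0.0242 and 0.0256, and all mice gave 0.0581, 0.0258 and 0.0602.

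Groups were taken from the labels: control, cuprizone with vehicle, and cuprizone with siponimod, with 5 mice each. Because the deposited values per mouse are TPM and not read counts, the branch of the planned design for counts was not used. TPM keep no depth, so precision is set by the spread between mice alone. Genes with a TPM in all 15 mice were used (19261), and genes above 0.5 TPM in at least 5 mice were tested (17714). Limma 3.58.1 in R 4.3.3 was fitted to log2(TPM + 0.5) with the 3 groups in 1 model (12 residual degrees of freedom), empirical Bayes moderation with a trend and Benjamini-Hochberg adjustment at 0.05, and adjusted p for genes are from limma. The pseudocount makes fold changes of genes with low TPM smaller than they were. Fold changes are given after subtraction of the median over genes of that comparison. Intervals are 95% limma intervals of the unshifted difference, moved by that median, without adjustment for the number of genes. Their width therefore includes shifts of whole libraries and is not the error of the relative change.

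Gene lists of cell types and pathways were fixed before the data were examined, 28 in number with 430 entries, of which 409 matched by symbol and 1 by another name. Blood-borne immune cells had fewer than 3 tested genes and the list was not tested. The other 27 lists were tested with camera (inter-gene correlation preset to 0.01, Benjamini-Hochberg over lists), with fry and with camera under an estimated correlation. Counts adjusted over the list alone used Benjamini-Hochberg within the list. Scores per mouse are the mean log2(TPM + 0.5) of a list's tested genes minus the median of that library over all tested genes. They were compared with exact permutation tests, a choice made after the data were examined. Gene names in the text follow a rule set before the data were examined. It takes the 10 largest rises and the 10 largest falls among called genes at or above the median expression, without predicted genes, the 3 members with the smallest adjusted p of each called list, and a fixed set that includes S1pr1, S1pr5, Mbp, Mog, Gfap, Aif1, Trem2 and Nefl. Some genes that the rule takes are not reported here. Genes that were the single call of a list, the authors' calls within lists, Hspa5 and Bc1 were named after their values were seen. Coordinates and transcript lengths came from GENCODE M21 on GRCm38, which covered 19259 genes. The other computations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

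The fit was tested on simulated data with 17714 genes and changes of known size in 200 of them. With all mice it recovered 66%, 61% and 61% of log2 changes of 1 in the vehicle against control, siponimod against control and siponimod against vehicle comparisons, and 12%, 10% and 13% of changes of 0.5, with 10, 3 and 9 false calls. Without vehicle mouse 1 and siponimod mouse 1 it recovered 94%, 96% and 84%, and 60%, 63% and 60%. Camera called the shifted list of simulated data (adjusted p = 1.34e-24) and 0 others. The simulated genes were drawn independently of each other, whereas the estimated correlation within the lists of these data was 0.16 to 0.90. This check therefore does not cover false calls of lists with correlated genes.

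Alternatives were no filter, a stricter filter, other thresholds, pseudocounts of 0.1 and 1, a fit of the 2 groups compared alone, the mouse number as a block and leaving out each mouse. After the data were examined, further ones were added: leaving out both cuprizone mice numbered 1, scaling each library to a common median, taking out Bc1, library weights, the authors' deposited calls and camera with an estimated correlation, also without both of those mice. Other splits of the mice were drawn with a fixed seed, 100 where there were more. Changes shared by the comparisons against control were set beside 100 simulated data sets and 20 splits of the control mice. In the simulations the residuals of whole mice were drawn with replacement over all groups. Vehicle mouse 1 could thus be absent, repeated or placed in another group.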

Results

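RNA of mixed corpus callosum and neocortex was sequenced from 15 wild-type mice in 3 groups of 5. Control mice had no treatment per the labels, so no cuprizone, and no vehicle is named for them. Cuprizone is a copper chelator that kills oligodendrocytes when fed to mice, and both other groups received 0.25% (w/w) of it for 3 weeks. Of these, 1 group was given vehicle (the vehicle mice) and the other siponimod at 3.125 mg/kg (the siponimod mice), a modulator of sphingosine 1-phosphate receptors 1 and 5. The labels name each mouse separately. Expression was available as TPM, transcript abundance scaled to a fixed total per library, which keeps no sequencing depth, so the depth of each library is unknown and no counting error is given. Genes with a TPM in all 15 mice summed to between 995381 and 996476 TPM per mouse, and 17714 of these 19261 genes passed the filter on low values and were tested.

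Vehicle mouse 1 stood apart from the other 14 libraries. Bc1, a small non-coding RNA of neuronal cytoplasm, took 35.1% of its TPM, against 6.0% to 10.8% in the other libraries. The median gene in that mouse had 4.48 TPM, against 9.64 to 10.6 TPM elsewhere, and transcripts of the mitochondrial genome took 11.3% of its TPM, against 14% to 17.4%. After each library was shifted to a common median, the 10% of genes with the shortest transcripts lay at a median of 0.76 log2 from the other vehicle mice. The 10% with the longest lay at -0.66. Before the shift, the median offset of vehicle mouse 1 from the mean of all mice was -0.84 log2, against 0.0034 to 0.084 in the other vehicle mice. The value of 0.76 is therefore not a rise in TPM. The median gene differed by -0.21 log2 between vehicle and control mice and by 0.21 log2 between siponimod and vehicle mice, and by 0.0083 log2 between siponimod and control mice. Without vehicle mouse 1 and siponimod mouse 1 (both mice numbered 1 of the cuprizone groups) these shifts were -0.030, 0.033 and 0.0078 log2. Fold changes are therefore given relative to the median gene of each comparison, on the scale of log2(TPM + 0.5). The p-values test the unshifted difference, and intervals keep the width of that difference.

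**Figure D1:**
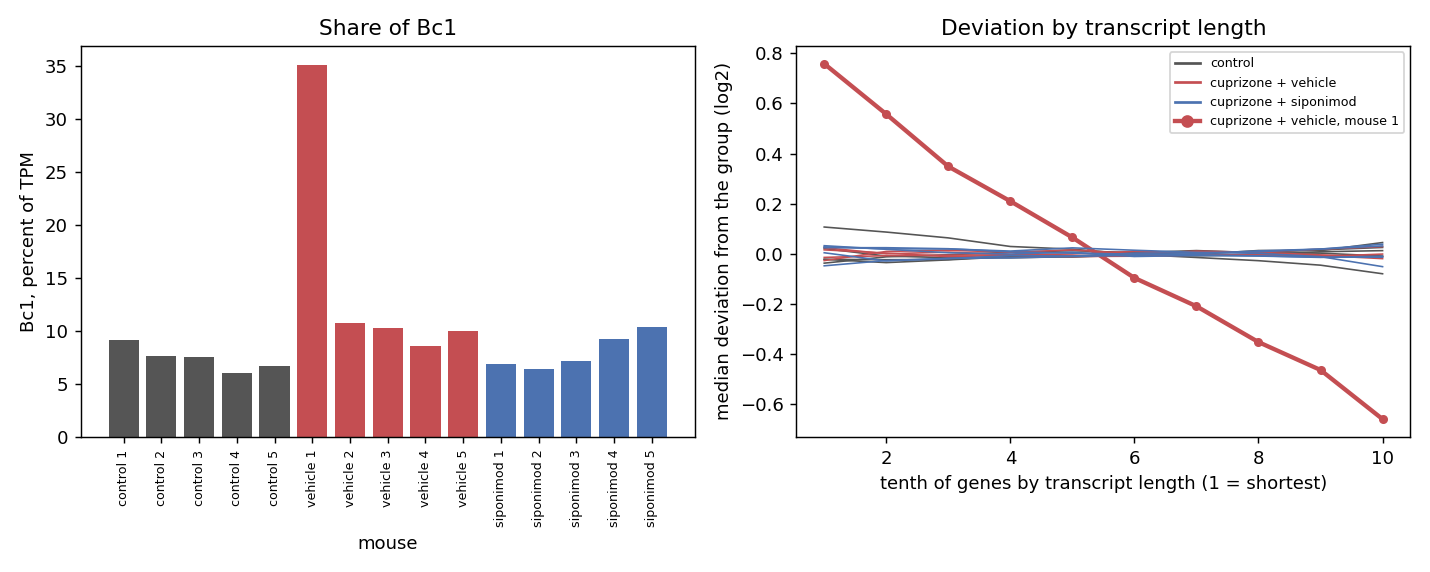
Share of TPM taken by Bc1 in each of the 15 mice (percent), and the median log2 deviation of each mouse from its group by transcript length in 10 bins of genes. Deviations were taken after each library was shifted to a common median. Vehicle mouse 1 had 35.1% of its TPM in Bc1 and its deviation ran from 0.76 in the bin of shortest transcripts to -0.66 in the bin of longest.

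The first comparison asked what differed in this tissue after 3 weeks of cuprizone with vehicle. Effects of the vehicle cannot be told apart from those of cuprizone here. In the vehicle mice 24 of 28 listed genes of myelin and mature oligodendrocytes fell, and 11 of 24 of disease-associated microglia, 5 of 17 of reactive astrocytes, 5 of 13 of complement and 6 of 18 of the integrated stress response rose. Tests of the lists as sets that allow for correlated genes held without vehicle mouse 1 and siponimod mouse 1 for myelin, complement and the stress response, and were lost for disease-associated microglia and reactive astrocytes (adjusted p = 0.0546 each, camera with an estimated correlation). Mbp, which encodes myelin basic protein (ENSMUSG00000041607, chromosome 18, 82475146 to 82585637, GRCm38), had 2208 ± 354 TPM in control mice and 408 ± 160 TPM in vehicle mice (mean ± SD, n = 5 each), a 4.93-fold fall relative to the median gene (adjusted p = 5.26e-05 in limma). Nupr1, a stress-induced chromatin regulator (ENSMUSG00000030717, chromosome 7, 126623249 to 126630861), rose 4.99-fold, from 15 ± 1.61 to 66.3 ± 6.09 TPM (adjusted p = 1.39e-08). Gfap, the intermediate filament of reactive astrocytes (ENSMUSG00000020932, chromosome 11, 102887336 to 102900912), rose 4.20-fold, from 89.5 ± 8.33 to 357 ± 195 TPM (adjusted p = 0.00168). For each of these 3 genes, every vehicle mouse lay beyond all 5 control mice.

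Among the 28 tested genes of the myelin and mature oligodendrocyte list, 24 fell, 0 rose and 4 did not pass, and 27 passed when adjusted over the list alone. The list median was -1.70 log2 (camera, adjusted p = 0.0118 with an estimated correlation). Mal, a raft protein of myelin, fell 7.66-fold (relative log2 fold change -2.94), Mog, a glycoprotein of the outer myelin surface, 6.0-fold (-2.58) and Fa2h, which makes the hydroxylated fatty acids of myelin lipids, 5.70-fold (-2.51). Mag, Cldn11 and Ugt8a fell by 2.56, 2.31 and 2.13 on the log2 scale. S1pr5, the sphingosine 1-phosphate receptor of oligodendrocytes that the series title names (ENSMUSG00000045087, chromosome 9, 21242912 to 21248443), fell 3.47-fold, from 15.6 ± 3.01 to 3.55 ± 1.03 TPM (adjusted p = 4.73e-06). It was the 1 called gene of 16 in the sphingosine 1-phosphate pathway list (2 when adjusted over the list alone). That list had a median of 0.07 and a mean of -0.06 log2 with a test that pointed down (adjusted p = 0.671, and 0.912 with an estimated correlation). Without vehicle mouse 1 and siponimod mouse 1, 2 of its genes rose and 2 fell, and 7 passed when adjusted over the list alone (adjusted p = 0.749 with an estimated correlation). S1pr1 had 84.6 ± 5.23 TPM in control and 88.2 ± 21.1 TPM in vehicle mice (relative log2 fold change 0.23, adjusted p = 0.942). Its level in vehicle mouse 1 lay below the other vehicle mice, as did the median gene of that library. Without that mouse S1pr1 passed at a relative change of 0.24 (adjusted p = 0.0232 in limma). Among 12 progenitor genes 0 were called (median -0.015, adjusted p = 0.671, and 0.912 with an estimated correlation). Among 12 genes of newly formed oligodendrocytes 1, Enpp6, fell (median -0.07, adjusted p = 0.118, and 0.763 with an estimated correlation).

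Of 24 tested genes of disease-associated microglia, a state of phagocytic microglia, 11 rose, 0 fell and 13 did not pass, and 17 passed when adjusted over the list alone (median 1.03 log2, adjusted p = 0.0118 with an estimated correlation). With both mice numbered 1 left out, 15 rose, 1 fell and 22 passed when adjusted over the list alone, but the list as a set no longer passed with an estimated correlation (median 0.88, adjusted p = 0.0546). Clec7a, a pattern recognition receptor, rose 14.1-fold from 0.254 ± 0.159 to 9.95 ± 7.13 TPM (adjusted p = 7.70e-05). Cst7, a cathepsin inhibitor, rose by 3.55 log2, and the integrin Itgax by 2.71. Trem2, a lipid-sensing receptor of microglia, rose from 14.8 ± 0.752 to 34.4 ± 12.4 TPM (2.51-fold, adjusted p = 0.0202). The Trem2 call was lost without control mouse 1, 2, 3 or 4 or vehicle mouse 5, with adjusted p between 0.0518 and 0.0593. Outside the lists, Cd52, a glycoprotein of leukocytes and microglia, rose by 2.65 log2 and Lyz2, the lysozyme of myeloid cells, by 1.69. Aif1, which encodes the pan-microglial marker IBA1, had 8.85 ± 0.721 TPM in control and 15.6 ± 5.10 TPM in vehicle mice (adjusted p = 0.0739). Aif1 passed without vehicle mouse 1 or 4, at adjusted p = 0.0232 and 0.0148. Of 14 homeostatic microglial genes 1, Fcrls, rose (2 when adjusted over the list alone, median 0.26, adjusted p = 4.89e-05, and 0.227 with an estimated correlation). In the fit without both mice numbered 1, 5 rose (8 when adjusted over the list alone, adjusted p = 0.183 with an estimated correlation). The Fcrls call was lost without any 1 of 9 mice: control mice 1, 4 and 5, vehicle mice 2, 3 and 5, and siponimod mice 2, 3 and 4 (adjusted p 0.0503 to 0.119). It was also lost with the mouse number as a block (0.0851) and with these groups fitted alone (0.115).

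The reactive astrocyte list had 5 of 17 genes higher and 0 lower, and 9 passed when adjusted over the list alone (median 0.96 log2, adjusted p = 0.0118 with an estimated correlation, lost at 0.0546 and a median of 0.87 without both mice numbered 1). Besides Gfap, the filament gene Vim rose by 1.58 log2 and the chemokine Cxcl10 by 2.53. Of 15 homeostatic astrocyte genes 0 were called (median 0.0026, adjusted p = 0.117, and 0.832 with an estimated correlation). Of the same genes, 5 rose and 1 fell without both mice numbered 1, and 7 passed when adjusted over the list alone (median 0.17, adjusted p = 0.000432, and 0.180 with an estimated correlation). Their mean score per mouse was 0.12 log2 above control (exact permutation p = 0.0159, adjusted p = 0.0306), and 0.14 without both mice (adjusted p = 0.0179). In the complement list 5 of 13 genes rose, among them C4b by 1.62 and C1qb by 1.19 log2, and 7 passed when adjusted over the list alone (median 0.89, adjusted p = 0.0118 with an estimated correlation). C4b has a near-identical copy, so its level is uncertain. Antigen presentation had 0 of 14 genes called and 4 when adjusted over the list alone (median 0.42, adjusted p = 0.0118 with an estimated correlation, lost at 0.0567 and a median of 0.37 without both mice numbered 1). In that latter fit 3 of its genes rose and 9 passed when adjusted over the list alone. Of 16 interferon response genes 0 were called, also when adjusted over the list alone (median 0.48, adjusted p = 3.27e-10, and 0.0688 with an estimated correlation). In the fit without both mice numbered 1, 1 rose and 4 passed when adjusted over the list alone (adjusted p = 0.136 with an estimated correlation).

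The integrated stress response, the programme driven by ATF4 after phosphorylation of eIF2 alpha, had 6 of 18 genes higher and 0 lower, and 10 passed when adjusted over the list alone (median 0.61 log2, adjusted p = 0.0118 with an estimated correlation). In the fit without both mice numbered 1, 11 rose and 12 passed when adjusted over the list alone. Atf5, a transcription factor of that response, rose 5.50-fold from 21.2 ± 3.32 to 105 ± 27.1 TPM (adjusted p = 2.24e-06). Gdf15, a secreted stress hormone, rose from 0.0899 ± 0.0987 to 2.82 ± 0.571 TPM (log2 fold change 2.70, adjusted p = 2.24e-06). Atf3 rose by 2.29 and was also the 1 called gene of 11 in the axonal injury list (2 when adjusted over the list alone, median 0.10, adjusted p = 0.0197, and 0.418 with an estimated correlation). Outside the lists, Cdkn1a, an inhibitor of the cell cycle, rose by 1.55 log2. Nefl, the light neurofilament of axons, had 284 ± 10.3 TPM in control and 250 ± 45.0 TPM in vehicle mice (relative log2 fold change 0.0017, 95% interval -0.24 to 0.24). Proliferation genes gave 0 calls of 15, and 4 when adjusted over the list alone (median 0.69, adjusted p = 0.0270 with an estimated correlation, lost at 0.136 and a median of 0.47 without both mice numbered 1). Top2a, a topoisomerase of dividing cells, had 0.723 ± 0.127 TPM in control and 2.24 ± 1.34 TPM in vehicle mice, and passed without vehicle mouse 1 (adjusted p = 0.0239, against 0.0673 with all mice). Haemoglobin and other erythrocyte genes gave 0 calls of 6, and 4 when adjusted over the list alone (median 1.77, adjusted p = 0.0225 with an estimated correlation, lost at 0.183 and a median of 1.53 without both mice numbered 1). The highest proliferation and erythrocyte scores of the vehicle mice were those of vehicle mouse 1 (-1.46 and 2.68). These scores are relative to the median gene of each library, which was lowest in that mouse. Haemoglobin genes have near-identical copies, and their single levels are uncertain.

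Cholesterol synthesis had 1 of 20 genes lower and 15 when adjusted over the list alone (median -0.38, adjusted p = 8.99e-09, and 0.273 with an estimated correlation). The fit without both mice numbered 1 had 13 lower, and 16 passed when adjusted over the list alone (median -0.29, adjusted p = 5.74e-17, and 0.0535 with an estimated correlation). The mean score per mouse was 0.30 log2 below control with all mice (exact permutation p = 0.00794, adjusted p = 0.0165) and without both (adjusted p = 0.0179). The gene called with all mice, Msmo1, fell by 0.30 log2 (adjusted p = 0.0258). The Msmo1 call was lost after scaling libraries to a common median (adjusted p = 0.519), after taking out Bc1 (0.166), and without control mouse 2, 3, 4 or 5 or vehicle mouse 2, 4 or 5 (0.0536 to 0.0896). Of 12 excitatory neuron genes 1 passed, and 2 when adjusted over the list alone (median -0.16, adjusted p = 0.00291, and 0.418 with an estimated correlation). It was Nrgn, a calmodulin-binding protein of dendrites, whose change relative to the median gene was -0.14 with a 95% interval of -0.31 to 0.04 that includes 0. The Nrgn call was lost without any of 13 single mice, all but vehicle mice 1 and 4 (adjusted p 0.0567 to 0.150). It was also lost with libraries scaled to a common median (0.711), Bc1 taken out (0.601), these groups fitted alone (0.215), the mouse number as a block (0.113), no filter (0.0613), genes at or above the median TPM alone (0.0534) and a pseudocount of 1 (0.0521). Nuclear genes of oxidative phosphorylation had 0 of 22 called and a median of 0.23 (adjusted p = 0.000434, and 0.273 with an estimated correlation). Their mean score, relative to each library's median gene, was 5.97 in vehicle mouse 1 and 4.55 to 4.64 in the other vehicle mice. The gap includes the low median gene of vehicle mouse 1. Without that mouse and siponimod mouse 1 the list median was -0.0043. The other lists were not called: inhibitory neuron (median 0.02 and a test that pointed down, adjusted p = 0.671), mitochondrial genome (median -0.01, mean 0.03, adjusted p = 0.671), endothelial and pericyte (-0.02, 0.671), choroid plexus and ependyma (-0.44, 0.364), striatum (-0.01, 0.992), hippocampus (-0.25, 0.671), immediate early genes (-0.30, 0.578), lipid efflux and storage (0.10, 0.0644) and Nrf2 targets (0.06, 0.0531, with Hmox1 higher). The mean scores per mouse of Nrf2 targets and of lipid efflux and storage were 0.36 and 0.24 log2 above control (exact permutation p = 0.00794, adjusted p = 0.0165 each, and 0.0179 each without both mice numbered 1).

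Over all 17714 genes, limma called 220 in this comparison, 75 higher and 145 lower (34.1% higher), and 1761 had an unadjusted p under 0.05. Scaling libraries to a common median gave 53.3% higher and taking out Bc1 gave 48.0% higher. Without vehicle mouse 1 the count was 652 (284 higher, 368 lower), and without it and siponimod mouse 1 it was 768 (344 higher, 424 lower), which held all 220. The authors' deposited table had 1418 genes at an adjusted p under 0.05, 821 higher and 597 lower. With its preset correlation, camera called 14 of 27 lists (11 up, 3 down), of which 8 held with an estimated correlation (myelin, disease-associated microglia, reactive astrocyte, stress response, complement, antigen presentation, erythrocyte and proliferation). The preset correlation again gave 14 lists without both mice numbered 1, but 3 passed with an estimated correlation: myelin (adjusted p = 0.0483), stress response (0.0321) and complement (0.0483).

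**Figure D2:**
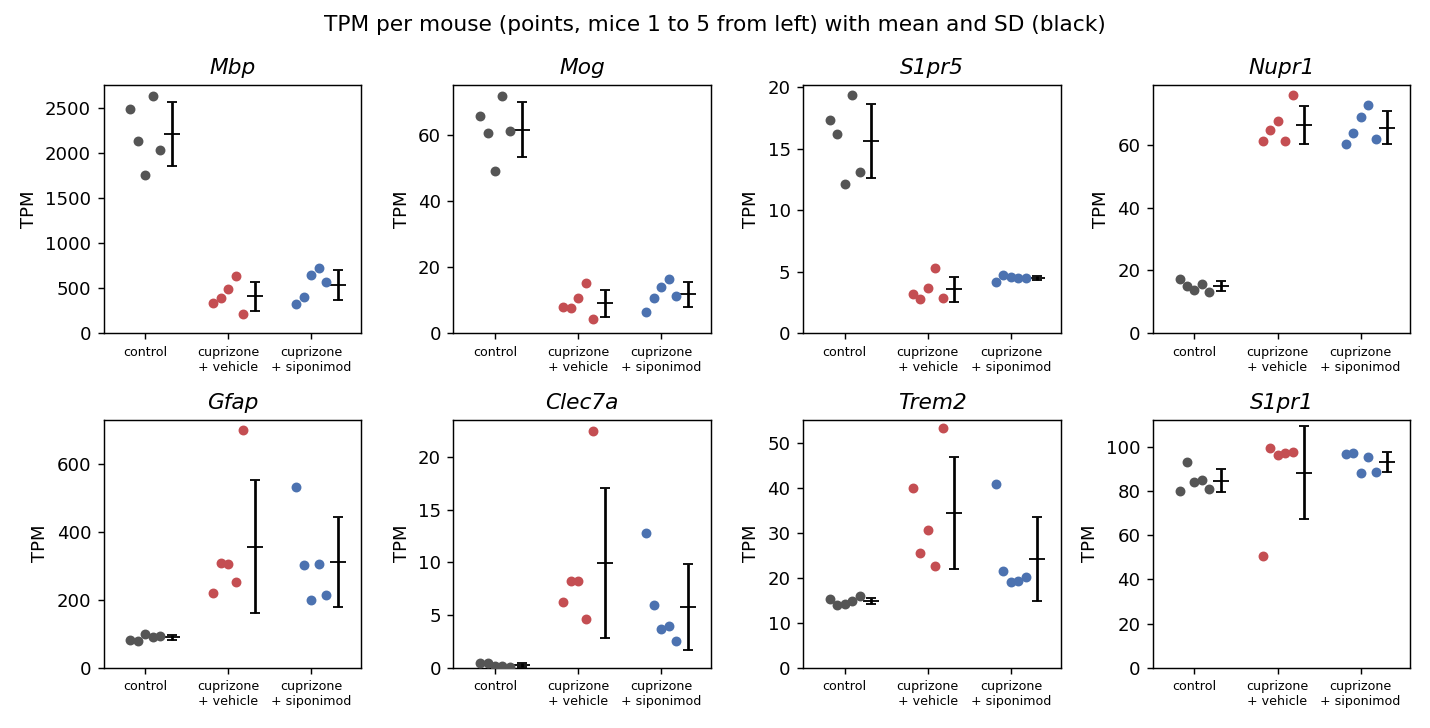
TPM of 8 genes in each of the 15 mice by group, with the mean and SD of 5 mice. The lowest control mouse had 1751 TPM of Mbp, above the 721 TPM of the highest cuprizone mouse, while S1pr1 had 84.6, 88.2 and 93.2 TPM on average in control, vehicle and siponimod mice.

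The next comparison set mice given cuprizone with siponimod against untreated control mice. Effects of cuprizone and of siponimod cannot be told apart in it. Against control, 22 of 28 listed myelin genes fell, and 9 of 18 of the stress response and 3 of 17 of reactive astrocytes rose; as a set, the reactive astrocyte list was not called without both mice numbered 1 (adjusted p = 0.170 with an estimated correlation, median 0.72 against 0.79 with all mice). Mbp fell 4.31-fold to 532 ± 167 TPM (n = 5, adjusted p = 0.000419). S1pr5 fell 3.22-fold to 4.47 ± 0.186 TPM (adjusted p = 3.56e-05), and S1pr1 was at 93.2 ± 4.53 TPM (relative log2 fold change 0.13, adjusted p = 1.00). Nupr1 rose 4.25-fold to 65.6 ± 5.18 TPM (adjusted p = 1.53e-08), and Gfap rose 3.24-fold to 312 ± 133 TPM (adjusted p = 0.00533).

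In the myelin and mature oligodendrocyte list 22 of 28 genes fell, 0 rose and 6 did not pass, and 25 passed when adjusted over the list alone (median -1.67 log2, adjusted p = 0.00247 with an estimated correlation). Ppp1r14a, a phosphatase inhibitor enriched in oligodendrocytes, fell 8.27-fold from 27.9 ± 4.12 to 2.97 ± 0.63 TPM, Mal fell 7.13-fold and Mog 5.32-fold. The integrated stress response had 9 of 18 genes higher and 0 lower, and 11 passed when adjusted over the list alone (median 0.64, adjusted p = 0.0138 with an estimated correlation). Its members Trib3, a pseudokinase, Gdf15 and Atf5 rose by 2.82, 2.75 and 2.44 log2. Cdkn1a rose by 1.75, Txnip, a regulator of thioredoxin, by 0.83 and the non-coding Snhg1 by 0.70. The Snhg1 call was lost with libraries scaled to a common median (adjusted p = 0.111). Mthfd2, an enzyme of mitochondrial folate metabolism, rose by 1.03, a call lost without siponimod mouse 2 or 5 (adjusted p = 0.0587 and 0.0568). Slc7a11, the cystine transporter, rose by 1.52 and Hmox1, haem oxygenase, by 1.59. These were the called members of 11 Nrf2 targets, 2 also when adjusted over the list alone (median 0.09, adjusted p = 0.00797, and 0.581 with an estimated correlation). The Slc7a11 call was lost without control mouse 1, 2 or 4 or siponimod mouse 1 or 2 (adjusted p 0.0543 to 0.0656), and that of Hmox1 without control mouse 1, 4 or 5 or siponimod mouse 1 or 2 (0.0527 to 0.0712) and with the mouse number as a block (0.0669).

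Reactive astrocyte genes had 3 of 17 higher, Gfap, Vim and Cxcl10, and 12 passed when adjusted over the list alone (median 0.79, adjusted p = 0.0365 with an estimated correlation, and 0.170 at a median of 0.72 without both mice numbered 1). Cxcl10 rose by 1.78 and Vim by 1.21 log2. The Vim call was lost without control mouse 2 or 4 or siponimod mouse 4 (adjusted p 0.0501 to 0.0591). Antigen presentation had 0 of 14 genes called and 6 when adjusted over the list alone (median 0.31, adjusted p = 0.0379 with an estimated correlation, and 0.152 at a median of 0.30 without both mice numbered 1). Of 24 disease-associated microglial genes 3 rose, and 13 passed when adjusted over the list alone (median 0.44, adjusted p = 8.30e-19, and 0.0919 with an estimated correlation). Clec7a rose by 2.88 to 5.78 ± 4.09 TPM (adjusted p = 0.000885), Itgax by 2.02 and Cst7 by 2.23. The Itgax call was lost without control mouse 1 (adjusted p = 0.0527), with a pseudocount of 1 (0.0590, at a change of 1.44) and with the mouse number as a block (0.0701). That of Cst7 was lost without any 1 of control mice 1 to 5, siponimod mice 1, 2 and 4 or vehicle mouse 3 (0.0562 to 0.124), with a pseudocount of 1 (0.115, at a change of 1.67) and with the block (0.0677). Trem2 was at 24.2 ± 9.37 TPM (relative log2 fold change 0.61, adjusted p = 0.640) and Aif1 at 11.2 ± 1.65 TPM (0.31, adjusted p = 1.00). Of 13 complement genes 1, C4b, rose, by 1.26, and 6 passed when adjusted over the list alone (median 0.45, adjusted p = 8.01e-09, and 0.0919 with an estimated correlation). Nefl was at 283 ± 17.9 TPM (relative log2 fold change -0.017, 95% interval -0.26 to 0.23).

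Further lists passed with the preset correlation of camera and lost the call with an estimated correlation, here given as median, adjusted p and adjusted p with an estimated correlation. Axonal injury, with Atf3 higher, had 0.02, 0.000448 and 0.267, and cholesterol synthesis, with 0 of 20 called, had -0.31, 2.82e-08 and 0.350. Axonal injury passed with an estimated correlation once both mice numbered 1 were left out (adjusted p = 0.0467), and there 2 cholesterol genes fell, with 12 when adjusted over the list alone (0.152 with an estimated correlation). Erythrocyte genes had 1.18, 0.000407 and 0.184, and interferon response genes 0.25, 3.02e-05 and 0.297. Newly formed oligodendrocytes had -0.09, 0.0194 and 0.581, homeostatic microglia 0.13, 0.0410 and 0.581, and homeostatic astrocytes 0.06, 0.0453 and 0.642. Choroid plexus and ependyma had -0.49, 0.00539 and 0.581, striatum -0.27, 0.000273 and 0.562, proliferation 0.16, 0.00979 and 0.581, and immediate early genes -0.29, 0.00760 and 0.617. In none of these except axonal injury was a gene called. The sphingosine 1-phosphate list, with S1pr5 as its 1 called gene, had a median of 0.0078 and a mean of -0.07 (adjusted p = 0.648). Inhibitory neuron genes had a median of -0.01 and a mean of 0.02 (adjusted p = 0.456). The remaining lists, oligodendrocyte progenitor, excitatory neuron, endothelial and pericyte, hippocampus, mitochondrial genome, oxidative phosphorylation, and lipid efflux and storage, had medians from -0.10 to 0.06 and 0 called genes.

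Limma called 132 genes, 37 higher and 95 lower (28% higher), and 827 had an unadjusted p under 0.05. The count rose to 490 without vehicle mouse 1, which is not in this comparison but shares the estimate of the spread, and to 508 when control and siponimod mice were fitted alone (51.0% higher). Without both mice numbered 1 of the cuprizone groups it was 350 (141 higher, 209 lower), with all 132 among them. The authors' deposited table had 991 genes at an adjusted p under 0.05, 491 higher and 500 lower. The preset correlation gave 18 of 27 lists (12 up, 6 down), and 4 held with an estimated correlation. These counts were 14 and 3 without both mice numbered 1, the 3 being myelin, stress response and axonal injury. In that fit the axonal injury list had 2 of 11 genes higher and a median of 0.041 log2, so a change of most of its genes was not shown.

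**Figure D3:**
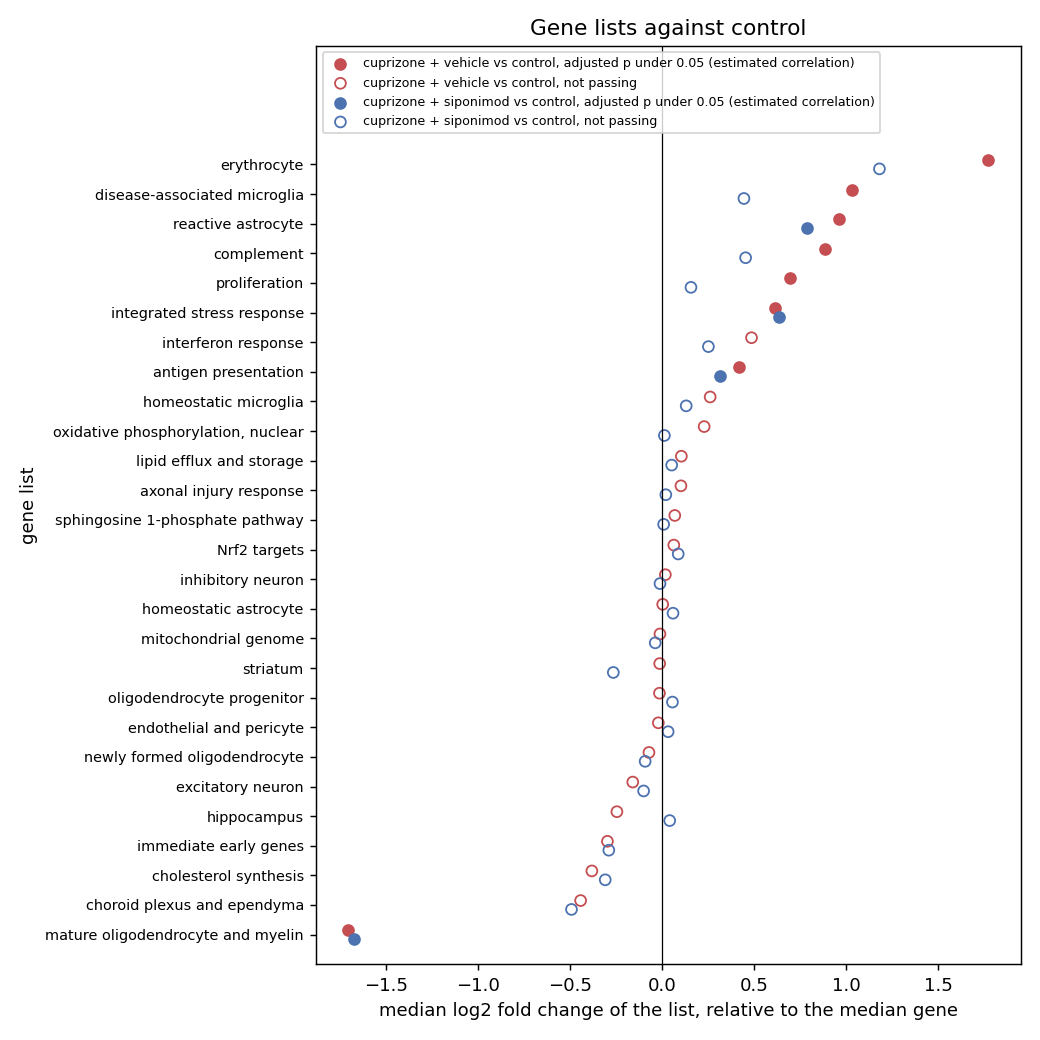
Median log2 fold change relative to the median gene of the 27 tested lists, in vehicle and in siponimod mice against control. Filled points passed with an estimated correlation and all mice, 8 lists in vehicle and 4 in siponimod mice, and the myelin list lay lowest at -1.70 and -1.67.

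The last comparison asked what siponimod changed in mice fed cuprizone. No gene passed: limma called 0 of 17714, with 874 at an unadjusted p under 0.05 and a smallest adjusted p of 0.496. The relative log2 difference between siponimod and vehicle mice was 0.20 for Mbp (95% interval -0.36 to 0.76), 0.18 for Mog (-0.41 to 0.77) and 0.12 for S1pr5 (-0.24 to 0.48). Trem2 was at 24.2 ± 9.37 TPM in siponimod and 34.4 ± 12.4 TPM in vehicle mice (n = 5 each), a relative log2 difference of -0.71 with a 95% interval of -1.20 to -0.22 that is not adjusted for the number of genes (adjusted p = 0.496).

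The stress response list had a median of 0.00096 (adjusted p = 0.457) and the myelin list one of 0.10 (adjusted p = 0.106), and 0 members of either were called. Nupr1 was at 65.6 and 66.3 TPM. Of the 12 lists that camera called with its preset correlation, 11 pointed down and 0 held with an estimated correlation. Disease-associated microglia had a median of -0.56 (adjusted p = 2.33e-24, and 0.126 with an estimated correlation), proliferation -0.30 (1.62e-15, and 0.126), complement -0.36 (5.04e-08, and 0.196), reactive astrocytes -0.33 (1.01e-05, and 0.507) and striatum -0.26 (3.40e-05, and 0.507). Erythrocyte genes had -0.57 (0.000559, and 0.318), interferon response -0.16 (0.000938, and 0.507), homeostatic microglia -0.09 (0.00120, and 0.507), antigen presentation -0.11 (0.0341, and 0.592) and the mitochondrial genome -0.09 (0.0399, and 0.592). Oxidative phosphorylation had -0.23 (4.34e-05, and 0.385) and 0.02 without both mice numbered 1, vehicle mouse 1 being the one with the high score. Excitatory neuron genes had 0.11 (0.0341, and 0.708). With all mice 0 genes of each of these lists passed, also when adjusted over the list alone. Without both mice numbered 1, 0 passed over all genes, while 12 of 24 disease-associated microglial, 6 of 13 complement, 4 of 15 proliferation and 3 of 14 homeostatic microglial genes passed when adjusted over the list alone, as did 4 inhibitory neuron and 2 endothelial and pericyte genes. The preset correlation then gave 14 lists, among them myelin (median 0.27, adjusted p = 1.95e-05, and 0.518 with an estimated correlation), cholesterol synthesis (0.14, 8.94e-06, and 0.354) and oxidative phosphorylation, which pointed up (0.0183, and 0.590), and again 0 held with an estimated correlation (0.282 for disease-associated microglia, complement and proliferation). Among their members, the relative log2 difference was -0.90 for Spp1 (19.3 ± 9.99 against 30.2 ± 10.6 TPM), -0.80 for Tyrobp, -1.30 for Cst7, -0.95 for Top2a, -0.85 for Ccnb2, -0.65 for C1qc and -0.61 for C1qa, each at an adjusted p of 0.496. Aif1 differed by -0.62, Gfap by -0.37 (95% interval -0.97 to 0.24), S1pr1 by -0.09 (-0.42 to 0.24) and Nefl by -0.01 (-0.25 to 0.23). Lists that were not called had a median, mean and test of different sign for newly formed oligodendrocytes (median 0.05, mean -0.04, adjusted p = 0.873), inhibitory neurons (-0.01, 0.0040, 0.178), axonal injury (-0.05, -0.04 and a test that pointed up, 0.373), sphingosine 1-phosphate (0.0051, -0.0055, 0.606) and Nrf2 targets (0.0049, -0.0041, 0.672). The remaining 8 lists had adjusted p between 0.0508 and 0.815.

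A test added after the data were examined compared the mean score of each list per mouse by exact two-sided permutation (252 assignments, smallest p 0.00794). Against control the myelin score differed by -1.61 in vehicle and by -1.56 in siponimod mice, the disease-associated microglial score by 1.38 and 0.80, the reactive astrocyte score by 1.20 and 0.87 and the stress response score by 1.02 and 1.02, each at exact permutation p = 0.00794 (adjusted p = 0.0165 and 0.0214). These p-values are the smallest possible. Without both mice numbered 1 the differences were -1.72 and -1.45 for myelin, 1.22 and 0.62 for disease-associated microglia, 1.08 and 0.72 for reactive astrocytes and 0.99 and 1.02 for the stress response. Other lists at the smallest p in both groups were complement (0.78 and 0.43), antigen presentation (0.52 and 0.37), axonal injury (0.38 and 0.32), Nrf2 targets (0.36 and 0.33) and cholesterol synthesis (-0.30 and -0.25), and without both mice numbered 1 their adjusted p was 0.0179 in vehicle and 0.0238 in siponimod mice (exact permutation). The axonal injury list had medians of 0.10 and 0.02 log2 against control with all mice, with Atf3 as its 1 called gene. In vehicle mice alone, proliferation (0.71), erythrocyte (1.33), homeostatic microglial (0.32) and lipid efflux (0.24) scores were at adjusted p = 0.0165, and at 0.0179, 0.0306, 0.0306 and 0.0179 without both mice (exact permutation). Homeostatic astrocytes differed by 0.12 and 0.10 (adjusted p = 0.0306 and 0.0357, and 0.0179 and 0.0536 without both mice, exact permutation). Interferon response passed in siponimod mice (0.26, adjusted p = 0.0214) and not in vehicle mice, where its difference was larger (0.48, adjusted p = 0.0571, exact permutation). Newly formed oligodendrocytes were at -0.18 in siponimod mice (adjusted p = 0.0357) and -0.11 in vehicle mice (0.328). Without both mice these lists were at 0.0390 and 0.0824 in siponimod mice, while erythrocytes moved from 0.143 to 0.0390 (exact permutation). Between siponimod and vehicle mice the microglial score differed by -0.58 (exact permutation p = 0.127), complement by -0.36 (p = 0.0952) and proliferation by -0.54 (p = 0.0952), with adjusted p of 0.571 for these 3 lists. When both mice numbered 1 were left out (70 assignments, smallest p 0.0286), the microglial score differed by -0.60 (exact permutation p = 0.0571, adjusted p = 0.386), and complement by -0.33, proliferation by -0.50 and homeostatic microglia by -0.14, each at p = 0.0286 (adjusted p = 0.257). The homeostatic microglial score differed by -0.20 with all mice (exact permutation p = 0.0635, adjusted p = 0.571).

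The authors' deposited table of this comparison had 279 genes at an adjusted p under 0.05, 192 higher and 87 lower in siponimod mice. Their deposited log2 fold changes were small, with a median size of 0.204 and 250 under 0.5. In the authors' deposited table the largest rises by the naming rule were Galnt9 (0.50), Nptx2, a secreted synaptic pentraxin (0.45), and Npas4, an activity-induced transcription factor (0.44), and Cldn5, the claudin of brain endothelium, rose by 0.32. The largest falls in the authors' deposited table were Prkcd, a protein kinase C isoform (-1.94), Tgfbr1 (-0.53) and Itga6 (-0.34). Of 27 myelin, 22 disease-associated microglial, 14 reactive astrocyte and 18 stress response genes in the authors' deposited table, 0 passed. Calls within lists in the authors' deposited table, named after their values were seen, were Itgam of complement (log2 fold change -0.42), Gpr34 of homeostatic microglia (-0.48), Slc17a7 and Slc30a3 of excitatory neurons (0.14 and 0.23), Fdps of cholesterol synthesis (0.17), Gap43 of axonal injury (0.17), Cldn5 and Slco1a4 of endothelium (0.32 and -0.32) and Npas4 of immediate early genes (0.44). All 279 had the same sign in limma without both mice numbered 1, and 256 with all mice, where 108 had an unadjusted p under 0.05. These genes were chosen in the same libraries, and the deposited fold changes matched TPM best without both mice. Shared signs were thus bound to be common and are no separate support. Without both mice numbered 1, limma again called 0 genes, with 1734 at an unadjusted p under 0.05 and a smallest adjusted p of 0.162. Library weights in limma gave 1 gene, Hspa5, an endoplasmic reticulum chaperone (relative log2 difference 0.30, adjusted p = 0.00677), named after its value was seen. On simulated data, the fit of this comparison recovered 61% of log2 changes of 1 and 13% of changes of 0.5, and 84% and 60% without both mice numbered 1. Smaller changes were not simulated.

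The question of whether siponimod reversed the cuprizone changes was put to the 220 genes called in vehicle mice. All 220 had the same sign in siponimod mice, and 65.9% had a smaller change there. Since these genes were chosen for their change in vehicle mice, smaller changes elsewhere are expected: data simulated without any siponimod effect gave a mean of 57.1% with a smaller change (16.8% to 92.5%, 38 of 100 simulations at or above the observed share) and 99.7% with the same sign. The share was 85.8% without both mice numbered 1, against a simulated mean of 65.6% (13 of 100 at or above). The slope of the siponimod on the vehicle change was 0.840. The same simulations gave a mean slope of 0.959 (SD 0.10), and 10 of 100 such simulations lay at or below the observed slope. For the 24 called myelin genes alone the slope was 0.955, and without both mice numbered 1 that of all called genes was 0.741, with 9 of 100 simulations at or below it. It was 0.831 without vehicle mouse 1 alone and 0.754 without siponimod mouse 1 alone, so the fall came mainly with siponimod mouse 1. That library did not stand apart in Bc1 share (6.9%), and its disease-associated microglial score (1.70) was the highest of the siponimod mice. Leaving it out thus moves the slope toward a siponimod effect. Both comparisons share the control mice. Over all tested genes their changes correlated at 0.707 with a covariance of 0.0509, across genes, which are not independent replicates. Simulated unchanged groups against the same controls gave a mean correlation of 0.440 (-0.615 to 0.895) and covariance of 0.0172, and simulated equal changes a mean of 0.813 and 0.0777, with 12 and 3 of 100 at or below the observed values. With the controls split between the comparisons, the mean over 20 splits was 0.432 for the correlation (0.324 to 0.513) and 0.0373 for the covariance. The comparisons shared 30 genes that rose and 92 that fell, against 0 and 0 in simulations of unchanged groups with the same controls and means of 204 (18 to 1278) and 158 (34 to 2964) in those of equal changes. The simulations of equal changes also called more genes, with means of 532 in vehicle and 579 in siponimod mice against 220 and 132 observed (32 and 11 of 100 at or below). Those of unchanged groups called up to 11561 and 15526 genes, with means of 116 and 155 that came from the largest count alone. Nearly all of them called 0 genes in each comparison. Their overlaps of 0 and 0 were thus all but fixed in advance and are no support for shared changes. Mice were redrawn across groups, so the spread in the simulations differs from that of the data. They therefore cannot decide whether siponimod reversed changes. In the fit without both mice numbered 1 the overlaps were 108 and 183 against simulated means of 342 and 339 (12 and 9 of 100 at or below), the correlation was 0.727 against 0.828 (10 of 100), the covariance 0.0472 against 0.0670 (3 of 100), and the calls 768 and 350 against 1165 and 1057 (37 and 3 of 100).

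**Figure D4:**
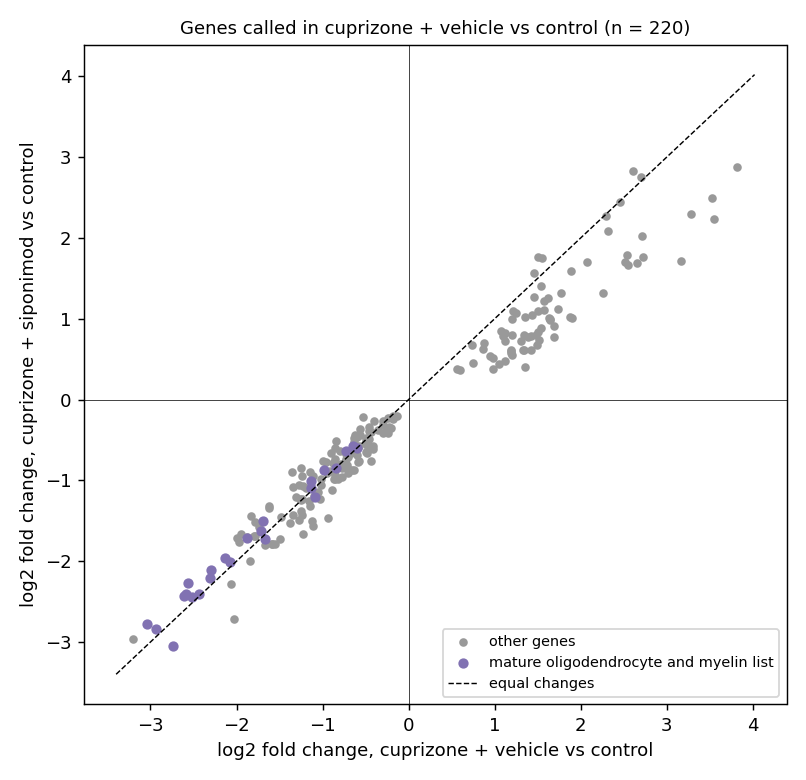
Relative log2 fold change against control of the 220 genes called in vehicle mice, in vehicle (x axis) and in siponimod mice (y axis), with the myelin list in purple and equal changes as a dashed line. All 220 genes lay on the same side of 0 in both, and 65.9% had a smaller change in siponimod mice, against a mean of 57.1% in simulations without a siponimod effect.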

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

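The tests of explanations and the other splits in this part were chosen only after the result they bear on was seen, except the test of the trend with transcript length, before which a correlation of the deposited fold changes with length had already been seen. Single mice were set against the others of their group by the gap to the nearest mouse over the group's range, which chance puts above 0.71 in about 1 in 20 groups of 5. Here 27 of 288 groups exceeded it, 16 of 201 for genes, 10 of 81 for list scores and 1 of 6 for library measures. Vehicle mouse 1 was the far mouse in 8 of them and siponimod mouse 1 in 7.

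Vehicle mouse 1 had the highest Bc1 share of its group (ratio 0.917) and the highest scores for nuclear oxidative phosphorylation (0.940) and homeostatic microglia (0.711). It was lowest for S1pr1 (0.951), Arc (0.773), Slc7a11 (0.755), Nefl (0.742) and Egr1 (0.720). Gene levels in this check were not shifted to a common median, whereas list scores are relative to each library's median gene. The median offset of that library was -0.84 log2, so these lows include a shift of the whole library. A loss of longer transcripts in that library may account for its distance. Its deviation correlated with transcript length across genes at a Spearman coefficient of -0.528, against -0.238 to 0.121 in the other 14 libraries. Bc1 lowering every other gene by 1 factor could not be the whole cause. The residual SD after scaling to a common median stayed at 0.618, against 0.200 to 0.274 elsewhere. Such a factor was a part of the offset. With Bc1 taken out, the median gene differed by -0.095 log2 between vehicle and control mice, against -0.21 with it. Between siponimod and vehicle mice these values were 0.11 and 0.21. The tables argue against a label swapped with a control mouse. No control mouse had Mbp at or below the highest cuprizone mouse (721 TPM), and vehicle mouse 1 had 328 TPM. No biological explanation was tested.

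The authors' deposited table called 279 genes between siponimod and vehicle mice, against 0 in limma. That the authors left out both mice numbered 1 could not be the whole cause, because limma called 0 genes without both first cuprizone mice as well. A trend of the deposited fold changes with transcript length was argued against, since 98.7% of the median size of the called changes was left after its removal (0.204 before, 0.201 after, bootstrap interval 94.1% to 101%). For the 1734 genes at an unadjusted p under 0.05 without both mice, chance was not excluded, since 2 of the 35 splits of the 8 mice gave as many and the highest other gave 1897. The authors' own test on their read counts, and small true effects of siponimod, stay open and were not tested.

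The list of disease-associated microglia was lower in siponimod than in vehicle mice by -0.58 in mean score. An effect of siponimod on these genes may be a cause but cannot be told apart from the spread between mice (exact permutation p = 0.127 with all mice, and 0.0571 for -0.60 without both mice numbered 1, where 12 of 24 genes passed when adjusted over the list alone and 0 over all genes). A single mouse as the source was argued against, since at least 72.3% of the difference was left with any 1 of the 10 mice left out (-0.42 without vehicle mouse 1 to -0.76 without siponimod mouse 1). Vehicle mice 1 and 5 had scores of 2.20 and 2.11, against 0.96 to 1.38 in the other vehicle mice and 0.64 to 1.70 in siponimod mice. These 2 vehicle mice as the main source stay open, since they were not left out together. More myelin kept in the siponimod mice could lower the list, but the myelin score differed between siponimod and vehicle mice by 0.046 with all mice (exact permutation p = 0.849) and by 0.27 without both mice numbered 1 (exact permutation p = 0.286), so more myelin was not shown. A relation also cannot be told apart from none: over 10 cuprizone mice the myelin and microglial scores had a Pearson r of -0.399 (permutation p = 0.255, Spearman rho -0.309, p = 0.386; adjusted p = 0.255 and 0.428 over 3 relations). The value depended on which mice were left out: r was 0.231 without vehicle mouse 5 and siponimod mouse 1, and -0.839 in the 8 mice without both mice numbered 1. No p-value was computed for these subsets, so a relation without vehicle mouse 1 stays open. That mouse had the highest microglial score (2.20) and the highest myelin score (1.23) of the 10.

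Siponimod mouse 1 was highest of its group for Trem2 (0.836), complement (0.835), proliferation (0.782), Aldoc (0.782) and C1qc (0.769), and lowest for Nefl (0.862) and the immediate early genes (0.762). Vehicle mouse 5 was highest for C4b (0.901) and Fcrls (0.734). Siponimod mouse 5 was highest for Hbb-bt (0.952) and siponimod mouse 4 for the hippocampus score (0.834). Control mouse 3 was lowest for Hba-a2 (0.795) and the erythrocyte score (0.781). Control mouse 5 was highest for Serpina3n (0.779) and the hippocampus score (0.714) and lowest for antigen presentation (0.716). Control mouse 1 was lowest for Arc (0.737) and Egr1 (0.719), and control mouse 2 highest for the mitochondrial genome score (0.874). Among 2028 genes without a TPM of all 15 mice, which no comparison here used, the authors' deposited table of vehicle against control mice called 39, of which 25 were higher.

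Splits of the same mice were fitted for each count, 100 with the real one among them, or all 35 for siponimod against vehicle mice without both mice numbered 1. Chance was called excluded where under 0.05 of the splits gave as many. The real split alone is the strongest result that 100 splits can give. Chance was excluded for the 220 genes of vehicle against control, since 1 of 100 splits, the real one, gave as many and the highest other gave 8, and for the 132 genes of siponimod against control (1 of 100, highest other 1). It was also excluded for 768 and 350 genes without both mice numbered 1 (1 of 100 each, highest other 250 and 219). At an unadjusted p under 0.05, however, siponimod against control gave 2051 genes in that fit and another split gave more, 2255 (2 of 100 as many). Chance was not excluded for the 874 genes at an unadjusted p under 0.05 between siponimod and vehicle mice, where 6 of 100 splits gave as many and the highest other gave 1082. For lists with the preset correlation of camera, 22 of 100 splits gave at least 14 in vehicle mice (highest other 17), 2 of 100 gave at least 18 in siponimod mice (highest other 18) and 30 of 100 gave at least 12 between these groups (highest other 15), so chance was excluded for the siponimod mice against control alone, where another split gave as many as the real one. Without both mice numbered 1 it was not excluded for lists in any comparison: 28 of 100 splits gave at least 14 in vehicle mice (highest other 18), 6 of 100 at least 14 in siponimod mice (highest other 15) and 3 of 35 at least 14 between these groups (highest other 14). With an estimated correlation it was excluded for 8 lists in vehicle mice (1 of 100, highest other 7) and for 4 in siponimod mice (1 of 100, highest other 2), and without both mice numbered 1 for 3 in each (1 of 100, highest other 1).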

How the results depend on the processing

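The settings added after the data were seen were leaving out both cuprizone mice numbered 1, scaling to a common median, taking out Bc1, library weights, the deposited calls, the estimated correlation, alone and with both mice left out, and other fits of lists and slope that were planned for genes alone. Of the values of named genes over all settings, 2799 kept their direction and side of the threshold, 102 lost and 66 gained a call, and 22 turned sign, none of them called in the fit with all mice. Depth is unknown for TPM, so its limit cannot be stated. Tests on counts and upper-quartile scaling were planned and not run, since counts were not used here, and planned checks for deposited tables without values per mouse did not apply. Unless stated, the cause was not tested.

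Genes changed in vehicle against control mice numbered 220. They were 84 among genes at or above the median TPM, 126 at an adjusted p under 0.01 and 140 with a log2 fold change of at least 1 in size, both stricter by construction, 390 with libraries scaled to a common median (208 higher, 182 lower), 727 with library weights, 768 without both mice numbered 1 and 1418 in the authors' deposited table. Leaving out 1 mouse gave 148 to 652. Genes changed in siponimod against control mice numbered 132, and by the same settings 43, 85, 87, 215, 518, 350 and 991, with 508 when those 2 groups were fitted alone and 97 to 490 with 1 mouse left out. Between siponimod and vehicle mice the count of 0 became 1 with library weights (Hspa5) and 279 in the authors' deposited table, and stayed at 0 to 0 with 1 mouse left out.

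Lists called numbered 14, 18 and 12 in these comparisons, 6, 4 and 0 with fry, 8, 4 and 0 with an estimated correlation, and 3, 3 and 0 with an estimated correlation and without both mice numbered 1. Leaving out both with the preset correlation gave 14, 14 and 14. With 1 mouse left out they were 14 to 16, 13 to 18 and 9 to 15. The slope of siponimod on vehicle changes was 0.840, 0.955 for the myelin list alone, which holds 24 of the 220 genes, and 0.754 to 0.917 with 1 mouse left out.

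Mouse numbers gave no sign of pairing: over 15 pairs of mice with the same number, deviations correlated at -0.0552 to 0.201, 2 pairs were over 0.1, and 4 of 15 mice correlated best with their own number. With the number as a block, 178, 111 and 0 genes and 15, 16 and 14 lists were called, and the slope was 0.859.

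Nefl in vehicle against control mice turned from 0.0017 to -0.012 without the filter, -0.020 with a pseudocount of 1, -0.022 with library weights, -0.052 without both mice numbered 1, and ranged from -0.052 to 0.035 with 1 mouse left out. In siponimod against control mice Nefl turned from -0.017 to 0.026 without both, 0.0017 with weights, and ranged from -0.043 to 0.026 with 1 mouse left out. Between siponimod and vehicle mice Nefl turned from -0.010 to 0.0036 without the filter, 0.011 with a pseudocount of 1, 0.083 without both, 0.029 with weights, and ranged from -0.045 to 0.039 with 1 mouse left out. Between the same groups, with 1 mouse left out, Mbp ranged from -0.066 to 0.37 and Mog from -0.098 to 0.38, negative without vehicle mouse 5.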

Other observations

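The relations below and their tests were chosen only after the data were seen. Over the 10 cuprizone mice, the myelin score and the reactive astrocyte score had a Pearson r of -0.481 (permutation p = 0.170, Spearman rho -0.285, p = 0.428) and the myelin and excitatory neuron scores one of 0.573 (permutation p = 0.0996, rho 0.370, p = 0.295). Over the 3 relations tested, the one for microglia included, adjusted p for r was 0.255 and for rho 0.428. Without vehicle mouse 5 and siponimod mouse 1, the mice farthest from the median myelin score, r was 0.360 and 0.210. In the 8 mice without both mice numbered 1, r was -0.800 and 0.544, so the sign for reactive astrocytes depended on which mice were left out. No p-value was computed for these subsets.

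In the authors' deposited table of siponimod against vehicle mice, fold changes correlated with transcript length at a Spearman coefficient of -0.132 across 13587 genes, which are not independent replicates. Genes called higher in the authors' deposited table had a median transcript length of 3551 nt, those called lower 4302 nt and all its genes 3533 nt.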
